A study of Rattus norvegicus with 9 samples.

How the data were processed

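RNA sequencing libraries of rat optic nerve were compared between healthy controls and a model of neuromyelitis optica spectrum disorder with optic neuritis, sampled 24 h or 7 d after aquaporin-4 antibody-positive serum had been placed in the sheath of the nerve. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the VAHTS Universal V6 kit. The genome build was mRatBN7.2 per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here.

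For each library the authors deposited whole-number read counts per gene, which were not normalized, and FPKM values per gene. The deposited FPKM were proportional to the count divided by the library total and 1 length per gene, with a largest relative deviation of 7.54e-07, so both files hold the same measurement. Each file held 23275 genes, named by symbol. Of these symbols, 20212 matched a symbol and 455 only a synonym in a RefSeq gene table of the GRCr8 assembly, which was used for names alone. Placeholder symbols numbered 6679, of which 2438 were tested. Genes of families with similar sequences, such as the MHC genes, share reads in ways the counts do not show, and without a stated strand setting reads of a gene and its antisense partner cannot be told apart.

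A count of 0 allows up to 3 counts, a floor that covers counting error only. Genes encoded in mitochondria took 5.30 to 9.17% of the counts. Replicates of a group were not copies of one another: the chi-square of their counts divided by its degrees of freedom was 45.0 to 362 in the 9 pairs.

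Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 16744 and removed 6531, libraries were scaled by TMM, and CPM values are TMM-scaled. All 9 libraries entered one fit by group (glmQLFit with robust estimation), with 6 residual degrees of freedom, since the groups are 1 experiment on 1 tissue. Both times were compared with control and with each other by edgeR's quasi-likelihood test, and a further test asked for any difference among the 3 groups. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 are said to have passed, risen or fallen. The comparison of 7 d with 24 h is also the test of whether the effects at the times differ.

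Gene lists (48) were fixed before the data were examined: lists of the cell types of the nerve, of immune cells, of pathways of injury and repair, and of other tissues a dissection could hold (skeletal muscle, fat, peripheral nerve, gland, epithelium, retina and blood). Ribosomal protein and mitochondrially encoded genes were included as checks. Lists share members: Lcn2, for example, is in the neutrophil, reactive astrocyte, IL-6 and iron lists. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 5 tested genes. Camera compares a list with all other genes. It was repeated with a correlation estimated per list. The rotation test fry asks whether the genes of a list move on balance one way, or in its mixed form either way, and does not compare the list with other genes. Medians of lists holding a gene at 0 counts in a group were also computed with that gene at the 3-count floor.

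The genes named in the text follow a rule fixed before the data were examined. Aqp4, Gfap, Mbp, Mog, Cd68, C3, Il6, S100a9, Lcn2 and Nefl are always given. Per comparison, the 8 largest rises and the 8 largest falls are named among genes that passed, had a mean of at least 5 CPM, did not overlap between the groups' libraries and had no placeholder symbol. Up to 4 genes per list are named by smallest unadjusted p. Genes named outside this rule, chosen after their values were seen, are those counted as changed at both times and transcripts of other tissues given per library.

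The procedure was tested on simulated counts with 16779 genes tested. For 24 h against control, 100 of 200 changed genes were recovered, all with the right sign, with 2 false calls. Recovery was 10.4, 62.7 and 77.3% for 2-fold, 4-fold and 8-fold changes. For 7 d against control, 103 of 200 were recovered with 5 false calls, at 7.46, 65.2 and 82.1% for these folds. For 7 d against 24 h, 216 of 400 were recovered with 15 false calls. Between unchanged groups 0 genes were called in either comparison with control. At 24 h both changed lists and 1 unchanged list were called. Simulated genes varied independently, so this does not test list calls in real libraries.

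Alternatives fixed beforehand were DESeq2 size factors and upper-quartile scaling; no count filter or a stricter one; DESeq2 1.42.0 and limma-voom with quality weights as tests; the deposited FPKM on a log2 scale with a pseudocount of 1 or 0.1; a block on replicate number; only the groups compared; a minimum log2 fold change of 1; camera on ranks; and each library left out in turn. Added after seeing the data were the removal of control replicate 2 with 24 h replicate 1, the removal of 24 h replicate 3 with 7 d replicate 3, the removal of each library's trend with gene length, and a list test without the genes of the other-tissue lists in the background. Overlap between the times was set against 40 simulations of unchanged groups sharing the controls. Some genes that the naming rule selects are not reported here. No coordinates are given, because the gene table available is of another assembly than the counts.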

Results

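Gene expression was measured by RNA sequencing of rat optic nerve in a model of optic neuritis of neuromyelitis optica spectrum disorder. In this disease, autoantibodies bind aquaporin-4, the water channel of astrocyte end-feet, and the optic nerve is a frequent site of damage. The model nerves had received serum positive for such antibodies under their sheath and were taken 24 h or 7 d later. Healthy nerves served as controls, so the serum and the injection itself cannot be separated. Each of the 3 groups had 3 libraries, described by the submitters as biological replicates. Total counts were 34697195 to 40618046 per library, and 3 counts were 0.0739 to 0.0865 CPM. Of 23275 genes, 16744 had enough counts to be tested. Levels are mean CPM ± SD with n = 3 per group. A change is its log2 fold change ± SE, with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test. SE is the change's size over the square root of that test's F. For a gene list, the median is that of its log2 fold changes, and the genes that passed are counted as higher or lower. A length-corrected adjusted p or median of a list has each library's trend with gene length removed, an alternative chosen after seeing the data.

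Some libraries carried transcripts of other tissues. Ckm, the muscle creatine kinase, was at 112 CPM in 24 h replicate 1 and at most 1.99 CPM in each other library. The retinal photoreceptor and Müller cell list had its highest summed level in control replicate 2, at 141 CPM against 56.0 to 124 CPM elsewhere. Krt14, an epithelial keratin, was at 8.26 CPM in 24 h replicate 2. The hypothalamic hormone transcript Oxt was at 109, 8.46 and 23.9 CPM in the controls and at most 2.42 CPM in the 6 model libraries.

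The first comparison asked how the nerve differed from healthy nerve 24 h after the injection. At 24 h, 14 of 26 reactive astrocyte genes, 9 of 15 neutrophil markers, 12 of 28 inflammatory cytokine genes and 11 of 50 cell cycle genes rose. Falls were found for 4 of 25 astrocyte markers, 4 of 30 myelinating oligodendrocyte markers and 3 of 16 mural cell markers. Timp1, an inhibitor of matrix metalloproteinases, rose from 22.1 ± 7.54 to 717 ± 147 CPM (log2 5.02 ± 0.44, adjusted p = 0.00181). Lcn2, which encodes the siderophore-binding protein lipocalin-2, rose from 2.64 ± 1.33 to 121 ± 74.1 CPM (log2 5.51 ± 0.69, adjusted p = 0.00657). Kcnj10, the inward rectifier potassium channel Kir4.1 of astrocytes, fell from 522 ± 38.5 to 216 ± 71.1 CPM (log2 −1.27 ± 0.26, adjusted p = 0.0281). Rgs5, a pericyte marker, fell from 26.1 ± 7.81 to 4.74 ± 0.814 CPM (log2 −2.46 ± 0.35, adjusted p = 0.0104).

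At 24 h, 906 of 16744 genes passed, 643 of them higher and 263 lower. Of these, 592 were higher and 226 lower by at least 2-fold. An unadjusted p under 0.05 was found for 4297 genes, and the libraries of the 2 groups did not overlap in 31.9% of genes, against 10% by chance. Leaving out 1 library moved the count: it was 39 (37 higher and 2 lower), 125 (88 and 37) and 35 (33 and 2) without control replicates 1, 2 and 3, 193 (163 and 30) without 24 h replicate 3 and 593 (447 and 146) without 7 d replicate 1. On all libraries, DESeq2 called 2581 genes (1516 higher and 1065 lower) and limma-voom with quality weights 1400 (890 and 510); limma on unfiltered FPKM called 325. Among 85 named genes that passed, 62, 48 and 66 lost the call without control replicates 1, 2 and 3, 8, 18 and 35 without 24 h replicates 1, 2 and 3, and 13, 9 and 4 without 7 d replicates 1, 2 and 3. The 16 that kept it throughout were Ucn2, Lcn2, Timp1, Gldn, Mmp3, Osmr, Il33, Cxcl1, Mcm3, Mcm6, Ldha, Hbegf, Fosl1, Myo5b, Clcf1 and S100a4. The count was 204 with control replicate 2 and 24 h replicate 1, the libraries with the highest sums of the retinal and skeletal muscle lists, both left out, an alternative chosen after seeing the data.

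The largest rises under the fixed naming rule were those of Ucn2, Cxcl3, Mcemp1, Mmp3, Gldn, S100a8, Spp1 and Mmp9. Gldn, the extracellular protein gliomedin, had the smallest adjusted p of all genes and rose from 0.420 ± 0.119 to 137 ± 49.9 CPM (log2 8.35 ± 0.42, adjusted p = 2.82e-05). Mmp3, a matrix metalloproteinase, rose from 0.0880 ± 0.0603 to 33.8 ± 6.01 CPM (log2 8.49 ± 0.83, adjusted p = 0.00300). Ucn2, a peptide of the corticotropin-releasing factor family, and the chemokine gene Cxcl3 were close to absent in the controls. Ucn2 went from 0.0195 ± 0.0170 to 27.8 ± 23.9 CPM (adjusted p = 0.00355), and Cxcl3 from 0.00901 ± 0.0156 to 10.8 ± 15.4 CPM (adjusted p = 0.0252). The largest falls were those of Oxt, Nat8f3, Chad, Slc25a18, Slc22a6, Lix1, Igf2 and Rgs5. Oxt went from 47.2 ± 54.3 to 0.0241 ± 0.0231 CPM (adjusted p = 0.0233). Igf2, an insulin-like growth factor made by the meninges, fell from 112 ± 53.8 to 19.0 ± 14.1 CPM (log2 −2.56 ± 0.54, adjusted p = 0.0297).

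Reactive astrocyte genes were higher, with 14 of 26 genes higher, 0 lower and 12 not passing (21 higher and 0 lower adjusted over the list alone, median 1.71, camera adjusted p = 3.04e-22, adjusted p = 0.0349 with an estimated correlation), the only one of the 48 lists whose call at 24 h held with an estimated correlation. Osmr, the oncostatin M receptor, rose from 7.75 ± 0.636 to 36.8 ± 8.94 CPM (log2 2.24 ± 0.27, adjusted p = 0.00543). Cd44, a hyaluronan receptor, rose from 96.8 ± 21.8 to 449 ± 141 CPM (log2 2.22 ± 0.27, adjusted p = 0.00615). Genes of the IL-6 and STAT3 response and the acute phase were higher too, with 9 of 24 genes higher, 0 lower and 15 not passing (18 higher and 0 lower adjusted over the list alone). Their median was 1.71 (camera adjusted p = 5.66e-12, adjusted p = 0.275 with an estimated correlation). Il6 itself, at 0.0357 ± 0.0381 CPM in control, 0.947 ± 0.978 at 24 h and 0.135 ± 0.0598 at 7 d, was left out by the count filter; without it, Il6 passed at 24 h (log2 4.59 ± 1.15, adjusted p = 0.0462) and not at 7 d (0.557). The astrocyte marker list was lower, with 0 of 25 genes higher, 4 lower and 21 not passing (1 higher and 7 lower adjusted over the list alone). Their median was −0.79 (camera adjusted p = 1.49e-05, adjusted p = 0.314 with an estimated correlation). The bicarbonate transporter gene Slc4a4 fell (log2 −1.73 ± 0.40, adjusted p = 0.0382), as did the folate enzyme Aldh1l1 (log2 −1.67 ± 0.42, adjusted p = 0.0499). The glial water and ion transport list was lower, with 0 of 22 genes higher, 3 lower and 19 not passing (2 higher and 8 lower adjusted over the list alone). Their median was −0.79 (camera adjusted p = 1.13e-04, adjusted p = 0.297 with an estimated correlation). Aqp4, the target of the serum, went from 2931 ± 1549.9 to 1471 ± 939 CPM (adjusted p = 0.338), and its libraries overlapped with the controls. Gfap, an intermediate filament gene of astrocytes, went from 5868 ± 1108 to 4924 ± 2007 CPM (adjusted p = 0.671).

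Myelinating oligodendrocyte markers were lower, with 0 of 30 genes higher, 4 lower and 26 not passing (0 higher and 13 lower adjusted over the list alone). Their median was −0.93 (camera adjusted p = 3.85e-10, adjusted p = 0.297 with an estimated correlation). Ermn, a cytoskeletal protein of myelin, fell from 742 ± 156 to 263 ± 97.0 CPM (log2 −1.50 ± 0.35, adjusted p = 0.0413). Fa2h, which hydroxylates myelin lipids, fell (log2 −1.21 ± 0.26, adjusted p = 0.0313), as did Opalin (log2 −1.26 ± 0.30, adjusted p = 0.0430) and Plekhh1 (log2 −1.39 ± 0.30, adjusted p = 0.0327). Mbp went from 38854 ± 7064 to 23579.8 ± 9175 CPM (adjusted p = 0.285) and Mog from 847 ± 106 to 406 ± 188 CPM (adjusted p = 0.105), both without passing although each 24 h library lay below the controls. Precursor and immature oligodendrocyte markers were lower as a list, with 0 of 19 genes passing (0 adjusted over the list alone). Their median was −0.59 (camera adjusted p = 0.00370, adjusted p = 0.295 with an estimated correlation), and the length-corrected median was −0.25 (adjusted p = 0.0241). Cholesterol biosynthesis genes were lower with 0 of 24 genes passing (0 adjusted over the list alone). Their median was −0.45 (camera adjusted p = 0.00287, adjusted p = 0.506 with an estimated correlation), a call lost without control replicate 2 (0.0669) or 24 h replicate 1 (0.0535). The myelinating markers summed to 125639, 146901 and 104637 CPM in the controls and 89777, 102099 and 42383 CPM at 24 h. Axonal injury and regeneration genes were higher, with 2 of 19 genes higher, 0 lower and 17 not passing (4 higher and 1 lower adjusted over the list alone). Their median was 0.29 (camera adjusted p = 0.0315, adjusted p = 0.275 with an estimated correlation). That call was lost without control replicate 1 (0.0526), control replicate 2 (0.0817) or 24 h replicate 1 (0.0652), on ranks (0.0629) and length-corrected (0.0937, median 0.16). Gal, the neuropeptide galanin, rose (log2 3.10 ± 0.52, adjusted p = 0.0164). Neuronal markers did not pass, with 0 of 15 genes passing (0 adjusted over the list alone, median −0.55, camera adjusted p = 0.0578), but the list did pass without control replicate 2 (0.0260), 24 h replicate 3 (0.0355), 7 d replicate 2 (0.0407) or 7 d replicate 3 (0.0345), without a count filter (0.0196) and length-corrected (0.0436). Nefl, the neurofilament light chain, went from 26.4 ± 13.9 to 20.4 ± 5.54 CPM (adjusted p = 0.665).

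The count filter left 15 of 27 neutrophil markers, and these were higher. They had 9 genes higher, 0 lower and 6 not passing (15 higher and 0 lower adjusted over the list alone). Their median was 5.58 (camera adjusted p = 1.45e-12, adjusted p = 0.275 with an estimated correlation). S100a9, a calcium-binding alarmin of neutrophils, rose from 0.884, 0.0944 and 0.243 CPM in the controls to 15.6, 7.70 and 119 CPM at 24 h (log2 6.81 ± 1.16, adjusted p = 0.0170). S100a8, its partner, rose (log2 7.51 ± 1.19, adjusted p = 0.0138), as did the protease inhibitor Slpi (log2 7.13 ± 1.24, adjusted p = 0.0180). The list's summed level was 1922 CPM in 24 h replicate 3 against 328 and 273 CPM in 24 h replicates 1 and 2. Erythrocyte markers were higher too, with 0 of 12 genes passing (0 adjusted over the list alone). Their median was 1.23 (camera adjusted p = 0.0422, adjusted p = 0.560 with an estimated correlation). That call was lost without control replicate 1 (0.119), control replicate 3 (0.0647), 24 h replicate 1 (0.220) or 24 h replicate 2 (0.225), and length-corrected (0.181, median 0.68). Their sums were 143, 1511 and 274 CPM in the controls and 1936, 2219 and 922 CPM at 24 h.

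Inflammatory cytokine and chemokine genes were higher, with 12 of 28 genes higher, 0 lower and 16 not passing (17 higher and 0 lower adjusted over the list alone). Their median was 2.56 (camera adjusted p = 1.31e-13, adjusted p = 0.275 with an estimated correlation). Ccl2, a chemoattractant of monocytes, rose from 4.25 ± 3.03 to 188 ± 181 CPM (log2 5.46 ± 0.82, adjusted p = 0.0121). The neutrophil chemokine Cxcl1 rose (log2 5.47 ± 0.65, adjusted p = 0.00534), the alarmin Il33 (log2 2.92 ± 0.30, adjusted p = 0.00337) and the cytokine Il11 (log2 6.21 ± 1.02, adjusted p = 0.0156). Targets and feedback genes of NF-kB were higher, with 7 of 19 genes higher, 0 lower and 12 not passing (10 higher and 0 lower adjusted over the list alone). Their median was 1.13 (camera adjusted p = 1.54e-09, adjusted p = 0.297 with an estimated correlation). The inflammasome and lytic cell death list was higher, with 3 of 19 genes higher, 0 lower and 16 not passing (7 higher and 1 lower adjusted over the list alone). Their median was 0.77 (camera adjusted p = 0.00208, adjusted p = 0.297 with an estimated correlation). Its member Ripk3, a kinase of necroptosis, rose (log2 2.31 ± 0.44, adjusted p = 0.0236), and Il1b rose (log2 5.24 ± 0.93, adjusted p = 0.0185).

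Phagocytic and lipid-handling macrophage genes were higher, with 8 of 26 genes higher, 0 lower and 18 not passing (17 higher and 1 lower adjusted over the list alone). Their median was 1.62 (camera adjusted p = 3.85e-10, adjusted p = 0.275 with an estimated correlation). Spp1, the secreted protein osteopontin, rose from 6.61 ± 1.41 to 1205 ± 1469.5 CPM (log2 7.51 ± 1.15, adjusted p = 0.0124), and its level in 24 h replicate 3 was 2901 CPM. Itgax rose (log2 3.28 ± 0.44, adjusted p = 0.00905), as did Lgals3, which encodes galectin-3, (log2 2.21 ± 0.31, adjusted p = 0.00918) and the scavenger receptor Msr1 (log2 4.47 ± 0.64, adjusted p = 0.0104). Monocyte and macrophage markers were higher, with 6 of 25 genes higher, 0 lower and 19 not passing (10 higher and 0 lower adjusted over the list alone). Their median was 1.27 (camera adjusted p = 4.10e-05, adjusted p = 0.297 with an estimated correlation). Among them Cd14 rose (log2 2.58 ± 0.37, adjusted p = 0.0104) and Arg1, arginase, rose (log2 4.52 ± 0.80, adjusted p = 0.0184), while Cd68 went from 9.49 ± 4.03 to 49.8 ± 57.9 CPM (adjusted p = 0.125). Fc receptor and immunoglobulin handling genes were higher, with 3 of 17 genes higher, 0 lower and 14 not passing (13 higher and 0 lower adjusted over the list alone). Their median was 1.53 (camera adjusted p = 1.95e-06, adjusted p = 0.297 with an estimated correlation). The inhibitory receptor Fcgr2b rose (log2 2.40 ± 0.54, adjusted p = 0.0351). Homeostatic microglia markers were lower as a list, with 0 of 17 genes passing (0 adjusted over the list alone). Their median was −0.52 (camera adjusted p = 0.00284, adjusted p = 0.297 with an estimated correlation).

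Complement genes moved both ways and the list did not pass, with 3 of 30 genes higher, 1 lower and 26 not passing (5 higher and 2 lower adjusted over the list alone, median 0.22, camera adjusted p = 0.127). It passed without control replicate 3 (0.0495). The anaphylatoxin receptor C5ar1 rose (log2 3.24 ± 0.74, adjusted p = 0.0376) and Itgam, a chain of complement receptor 3, rose (log2 1.59 ± 0.36, adjusted p = 0.0351), whereas C3 fell from 321 ± 75.6 to 93.6 ± 54.5 CPM (log2 −1.78 ± 0.45, adjusted p = 0.0487). Interferon-stimulated genes were higher, with 3 of 44 genes higher, 0 lower and 41 not passing (3 higher and 0 lower adjusted over the list alone). Their median was 0.53 (camera adjusted p = 6.09e-05, adjusted p = 0.381 with an estimated correlation). The GTPase gene Gbp2 rose (log2 1.90 ± 0.31, adjusted p = 0.0156). MHC class II genes did not pass as a list, with 1 of 17 genes higher, 0 lower and 16 not passing (2 higher and 3 lower adjusted over the list alone, median −0.66, camera adjusted p = 0.851). The member that rose was Lgmn (log2 1.61 ± 0.36, adjusted p = 0.0343), a lysosomal protease, while the invariant chain Cd74 went from 284 ± 139 to 80.0 ± 6.11 CPM (adjusted p = 0.0847). The MHC class I list had 0 of 23 genes passing (0 adjusted over the list alone, median 0.22, camera adjusted p = 0.167). It passed without control replicate 3 (0.0265). T cell markers had a negative median and camera direction but a mean of 0.03, with 1 of 19 genes higher, 0 lower and 18 not passing (1 higher and 0 lower adjusted over the list alone, median −0.49, camera adjusted p = 0.809). The costimulatory receptor Icos rose (log2 2.82 ± 0.64, adjusted p = 0.0365). B and plasma cell markers had 0 of 6 genes passing (0 higher and 1 lower adjusted over the list alone, median −0.70, camera adjusted p = 0.311), NK and cytotoxic markers 0 of 6 genes passing (1 higher and 1 lower adjusted over the list alone, median −0.84, camera adjusted p = 0.497) and mast cell markers 0 of 5 genes passing (1 higher and 1 lower adjusted over the list alone, median 0.10, camera adjusted p = 0.993). The filter left 6 of 16, 6 of 16 and 5 of 12 members. Setting Eomes, with 0 counts at 24 h, to the 3-count bound changed the NK median to −0.79.

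Cell cycle genes were higher, with 11 of 50 genes higher, 0 lower and 39 not passing (19 higher and 0 lower adjusted over the list alone). Their median was 1.25 (camera adjusted p = 5.18e-14, adjusted p = 0.297 with an estimated correlation). Of the replicative helicase genes, Mcm5 rose from 2.95 ± 1.01 to 36.1 ± 7.74 CPM (log2 3.61 ± 0.48, adjusted p = 0.00905), Mcm3 (log2 2.69 ± 0.30, adjusted p = 0.00450) and Mcm6 (log2 2.98 ± 0.36, adjusted p = 0.00595). Apoptosis and p53 target genes were higher, with 8 of 26 genes higher, 0 lower and 18 not passing (19 higher and 1 lower adjusted over the list alone, median 1.05, camera adjusted p = 6.69e-08, adjusted p = 0.295 with an estimated correlation), among them the growth arrest gene Gadd45a (log2 2.86 ± 0.52, adjusted p = 0.0201) and the cyclin gene Ccng1 (log2 1.43 ± 0.30, adjusted p = 0.0285). The heat shock list had 6 of 17 genes higher, 0 lower and 11 not passing (7 higher and 0 lower adjusted over the list alone). Their median was 0.55 (camera adjusted p = 2.30e-07, adjusted p = 0.275 with an estimated correlation). Hspb1, a small chaperone, rose (log2 2.57 ± 0.41, adjusted p = 0.0148), as did the mitochondrial chaperonin Hspd1 (log2 1.11 ± 0.22, adjusted p = 0.0246). Unfolded protein and integrated stress response genes had 7 of 26 genes higher, 0 lower and 19 not passing (11 higher and 0 lower adjusted over the list alone, median 0.69, camera adjusted p = 2.55e-05, adjusted p = 0.297 with an estimated correlation), with rises of the transcription factor Atf4 (log2 1.28 ± 0.28, adjusted p = 0.0313) and asparagine synthetase, Asns (log2 1.80 ± 0.36, adjusted p = 0.0266). Immediate early genes had 4 of 25 genes higher, 0 lower and 21 not passing (7 higher and 0 lower adjusted over the list alone, median 0.99, camera adjusted p = 7.26e-05, adjusted p = 0.373 with an estimated correlation), led by the AP-1 subunit Fosl1 (log2 6.76 ± 0.76, adjusted p = 0.00450).

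Iron, haem and ferroptosis genes were higher, with 5 of 31 genes higher, 0 lower and 26 not passing (6 higher and 0 lower adjusted over the list alone). Their median was 0.74 (camera adjusted p = 1.49e-05, adjusted p = 0.275 with an estimated correlation), and the length-corrected median was 0.43. Hmox1, which breaks down haem, rose from 10.2 ± 2.20 to 141 ± 63.4 CPM (log2 3.79 ± 0.48, adjusted p = 0.00774). The hypoxia and glycolysis list had 4 of 27 genes higher, 0 lower and 23 not passing (7 higher and 2 lower adjusted over the list alone). Their median was 0.36 (camera adjusted p = 0.0137, adjusted p = 0.429 with an estimated correlation), a call lost on ranks (0.0714). Ldha, lactate dehydrogenase, rose from 107 ± 17.3 to 891 ± 281 CPM (log2 3.06 ± 0.32, adjusted p = 0.00337). Oxidative phosphorylation genes had 2 of 38 genes higher, 0 lower and 36 not passing (2 higher and 0 lower adjusted over the list alone, median 0.39, camera adjusted p = 1.19e-04, adjusted p = 0.538 with an estimated correlation), among them Cox5a (log2 1.47 ± 0.29, adjusted p = 0.0260). That call was lost length-corrected (0.237, median 0.09). Genes encoded in mitochondria did not pass, with 0 of 13 genes passing (0 adjusted over the list alone, median −0.01, camera adjusted p = 0.851) and a mean of 0.07, with camera's direction up. Ribosomal protein genes were higher, with 4 of 84 genes higher, 0 lower and 80 not passing (6 higher and 0 lower adjusted over the list alone). Their median was 0.77 (camera adjusted p = 1.16e-16, adjusted p = 0.373 with an estimated correlation). Their median stayed positive under the other scalings tried, at 0.76 and 0.73 (length-corrected 0.36), and Rps27l rose (log2 1.72 ± 0.24, adjusted p = 0.00918) and Rpl10a (log2 1.21 ± 0.29, adjusted p = 0.0434). Short genes were higher than long ones at 24 h: across 11273 genes, the log2 fold change and the gene length had a Spearman correlation of −0.355.

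Mural cell markers were lower, with 0 of 16 genes higher, 3 lower and 13 not passing (0 higher and 3 lower adjusted over the list alone). Their median was −0.53 (camera adjusted p = 2.27e-04, adjusted p = 0.275 with an estimated correlation). Besides Rgs5 the falls were those of Vtn (log2 −2.14 ± 0.45, adjusted p = 0.0297) and the smooth muscle myosin light chain Myl9 (log2 −1.76 ± 0.41, adjusted p = 0.0394). Endothelial and blood-nerve barrier markers were lower, with 0 of 23 genes higher, 1 lower and 22 not passing (0 higher and 3 lower adjusted over the list alone). Their median was −0.48 (camera adjusted p = 0.0112, adjusted p = 0.384 with an estimated correlation), a call lost without 24 h replicate 1 (0.0701) or 24 h replicate 2 (0.0645). Angiogenesis and endothelial activation genes were higher, with 6 of 25 genes higher, 0 lower and 19 not passing (7 higher and 0 lower adjusted over the list alone). Their median was 0.71 (camera adjusted p = 8.56e-04, adjusted p = 0.297 with an estimated correlation). Plau, the urokinase, rose (log2 2.68 ± 0.44, adjusted p = 0.0156). Fibroblast and meningeal markers were lower, with 1 of 23 genes higher, 2 lower and 20 not passing (1 higher and 5 lower adjusted over the list alone, median −0.66, camera adjusted p = 0.00158, adjusted p = 0.376 with an estimated correlation), although their member Mgp, a matrix protein, rose (log2 1.96 ± 0.46, adjusted p = 0.0413). Extracellular matrix and scar genes were higher, with 5 of 36 genes higher, 1 lower and 30 not passing (10 higher and 1 lower adjusted over the list alone). Their median was 0.48 (camera adjusted p = 3.06e-04, adjusted p = 0.373 with an estimated correlation), a call lost without both control replicate 2 and 24 h replicate 1 (0.344), a choice made after seeing the data. Tnc, tenascin C, rose (log2 4.46 ± 0.77, adjusted p = 0.0171) and Lox, which crosslinks collagen, rose (log2 2.93 ± 0.41, adjusted p = 0.00918). Neurotrophic and growth factor genes were higher, with 4 of 25 genes higher, 1 lower and 20 not passing (6 higher and 3 lower adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.0168, adjusted p = 0.373 with an estimated correlation), a call lost without control replicate 2 (0.0599) or 24 h replicate 1 (0.0775) and on ranks (0.142). Hbegf, a ligand of the EGF receptor, rose (log2 2.44 ± 0.22, adjusted p = 0.00181) and the cytokine Clcf1 rose (log2 5.82 ± 0.51, adjusted p = 0.00181).

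Skeletal muscle markers were called higher, with 0 of 23 genes passing (13 higher and 0 lower adjusted over the list alone, median 4.62, camera adjusted p = 0.00287, adjusted p = 0.560 with an estimated correlation), but their sum was 1250 CPM in 24 h replicate 1 against 21.8 to 42.6 CPM in the other libraries. Without that library the list was lower and not called (0.347). Schwann cell markers had a mean of 0.26 and camera's direction was up, with 2 of 17 genes higher, 0 lower and 15 not passing (2 higher and 0 lower adjusted over the list alone, median −0.15, camera adjusted p = 0.698). Pmp2, a lipid carrier of peripheral myelin, rose (log2 2.89 ± 0.38, adjusted p = 0.00905). Keratinised epithelium markers had 1 of 10 genes higher, 0 lower and 9 not passing (1 higher and 0 lower adjusted over the list alone, median 1.78, camera adjusted p = 0.164), with a rise of the desmosomal Dsg3 (log2 2.89 ± 0.70, adjusted p = 0.0437), and passed without 24 h replicate 3 (0.0138). Their sum was 227 CPM in 24 h replicate 2 against 8.56 to 45.7 CPM in the other libraries. The retinal photoreceptor and Müller cell list had 0 of 6 genes passing (0 higher and 1 lower adjusted over the list alone, median −0.66, camera adjusted p = 0.0842) and passed without control replicate 1 (0.0416) or a count filter (0.00914) and length-corrected (0.0355). Adipocyte markers had 0 of 9 genes passing (0 adjusted over the list alone, median −0.51, camera adjusted p = 0.460) and a mean of 0.02, with camera's direction down. The lacrimal and Harderian gland list had 0 of 8 genes passing (1 higher and 0 lower adjusted over the list alone, median 1.36, camera adjusted p = 0.131) and passed without 24 h replicate 3 (0.0248). Its sum was 68.0 CPM in 24 h replicate 2 against 19.6 to 40.8 CPM in the other libraries.

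In all, camera called 34 of 48 lists at 24 h, 25 higher and 9 lower. Its preset correlation assumes that the genes of a list vary nearly independently, and with an estimated correlation 1 call held. The rotation test fry, which asks only whether the genes of a list move on balance one way, called 17 lists.

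**Figure D1:**
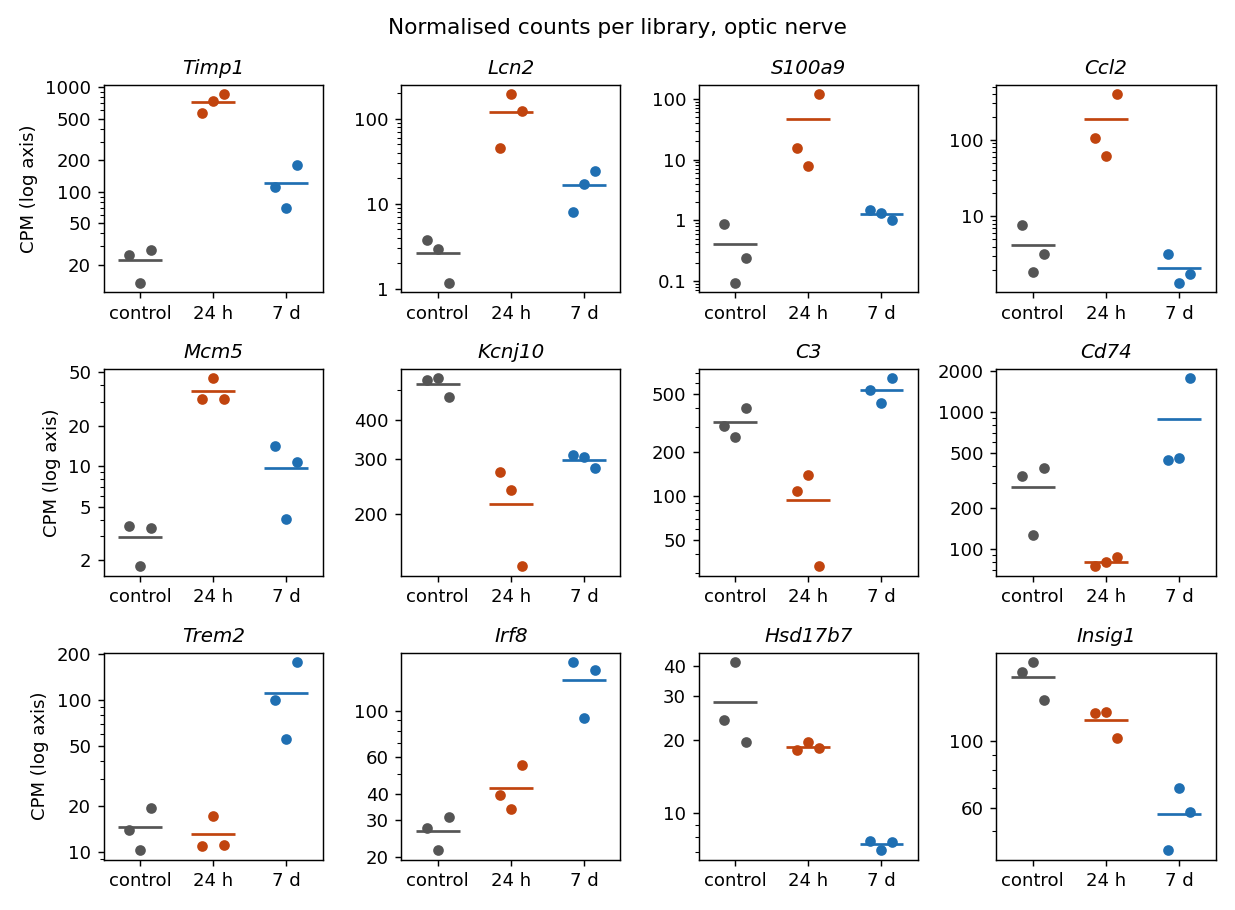
CPM of 12 genes in each library on log axes, with a line at each group's mean; points are the 3 libraries of the control, 24 h and 7 d groups. Timp1 lay at 22.1 CPM in control, 717 CPM at 24 h and 121 CPM at 7 d.

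The second comparison asked how the nerve differed from healthy nerve 7 d after the injection. Few single genes passed: 1 of 26 phagocytic macrophage genes and 1 of 25 monocyte and macrophage markers rose, and 3 of 24 cholesterol biosynthesis genes fell. Trem2, a lipid receptor of microglia, rose from 14.6 ± 4.70 to 111 ± 62.3 CPM (log2 2.93 ± 0.43, adjusted p = 0.0404). Irf8, a transcription factor of microglia and monocytes, rose from 26.8 ± 4.83 to 140.0 ± 42.1 CPM (log2 2.38 ± 0.30, adjusted p = 0.0401). Insig1, a regulator of sterol synthesis, fell from 164 ± 23.8 to 57.0 ± 13.3 CPM (log2 −1.52 ± 0.23, adjusted p = 0.0432).

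At 7 d, 33 genes passed, 29 higher and 4 lower, each by at least 2-fold, with a smallest adjusted p of 0.0401. An unadjusted p under 0.05 was found for 2355 genes, and the libraries of the 2 groups did not overlap in 23.4% of genes, against 10% by chance. edgeR's count was 0 without control replicate 1, 2 or 3 (2286, 1459 and 1954 genes at an unadjusted p under 0.05), 24 h replicate 1 or 2 (2372 and 2475), or 7 d replicate 1 or 3 (1627 and 1624), and was 172 without 24 h replicate 3 and 181 without 7 d replicate 2. It was also 0, with 1429 genes at an unadjusted p under 0.05, when control replicate 2 and 24 h replicate 1 were both left out, a choice made after seeing the data; on all libraries DESeq2 called 806 genes, limma-voom with quality weights 428, edgeR with only these 2 groups in the fit 1, not among the 33, and limma on unfiltered FPKM 0 (2563 at an unadjusted p under 0.05). All 18 named genes that passed at 7 d lost the call in each of the 7 fits with a count of 0.

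The 8 largest rises were those of Trem2, Plau, Myo7a, Cd34, Timp1, Htatip2, Irf8 and Cd180. Cd180, a Toll-like receptor relative of B cells and macrophages, rose from 9.04 ± 0.163 to 42.8 ± 12.9 CPM (log2 2.24 ± 0.26, adjusted p = 0.0401). Cd34, a sialomucin of endothelial and progenitor cells, rose from 12.1 ± 1.86 to 72.4 ± 30.4 CPM (log2 2.58 ± 0.38, adjusted p = 0.0404). Timp1 rose (log2 2.45 ± 0.39, adjusted p = 0.0467), as did Plau (log2 2.82 ± 0.44, adjusted p = 0.0467), Myo7a (log2 2.59 ± 0.34, adjusted p = 0.0401) and Htatip2 (log2 2.39 ± 0.38, adjusted p = 0.0467). Among the 4 genes that fell were Insig1, Hsd17b7 (log2 −1.91 ± 0.28, adjusted p = 0.0404), a sterol biosynthesis enzyme, and Aacs (log2 −1.86 ± 0.27, adjusted p = 0.0404), which feeds ketone bodies into lipid synthesis.

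Cholesterol biosynthesis genes were lower, with 0 of 24 genes higher, 3 lower and 21 not passing (0 higher and 20 lower adjusted over the list alone). Their median was −1.32 (camera adjusted p = 2.12e-26, adjusted p = 0.125 with an estimated correlation). Myelinating oligodendrocyte markers were also lower, with 0 of 30 genes passing (0 higher and 3 lower adjusted over the list alone). Their median was −0.59 (camera adjusted p = 1.84e-06, adjusted p = 0.404 with an estimated correlation). Mbp went from 38854 ± 7064 to 29736 ± 10123 CPM (adjusted p = 0.657) and Mog from 847 ± 106 to 533 ± 132 CPM (adjusted p = 0.423). The precursor list did not pass, with 0 of 19 genes passing (0 adjusted over the list alone, median −0.00, camera adjusted p = 0.452) and a mean of 0.12, with camera's direction up.

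Phagocytic and lipid-handling macrophage genes were higher, with 1 of 26 genes higher, 0 lower and 25 not passing (16 higher and 1 lower adjusted over the list alone). Their median was 1.28 (camera adjusted p = 1.61e-17, adjusted p = 0.125 with an estimated correlation). The lysosomal protease gene Ctsd went from 379 ± 39.9 to 2169.7 ± 1046 CPM (adjusted p = 0.0699). Homeostatic microglia markers were higher, with 0 of 17 genes passing (8 higher and 0 lower adjusted over the list alone). Their median was 0.88 (camera adjusted p = 1.20e-08, adjusted p = 0.125 with an estimated correlation). The fractalkine receptor Cx3cr1 went from 29.9 ± 7.65 to 92.5 ± 26.8 CPM (adjusted p = 0.0712) and the growth factor receptor Csf1r from 221 ± 51.9 to 633 ± 199 CPM (adjusted p = 0.0942). Monocyte and macrophage markers were higher, with 1 of 25 genes higher, 0 lower and 24 not passing (8 higher and 0 lower adjusted over the list alone). Their median was 0.94 (camera adjusted p = 2.41e-08, adjusted p = 0.242 with an estimated correlation). Aif1, which encodes Iba1, rose from 45.1 ± 10.9 to 160.4 ± 42.7 CPM (log2 1.83 ± 0.27, adjusted p = 0.0404). Fc receptor genes had 0 of 17 genes passing (15 higher and 0 lower adjusted over the list alone). Their median was 1.69 (camera adjusted p = 2.77e-15, adjusted p = 0.146 with an estimated correlation). Complement genes had 0 of 30 genes passing (7 higher and 0 lower adjusted over the list alone). Their median was 0.76 (camera adjusted p = 8.11e-08, adjusted p = 0.125 with an estimated correlation). C1qb went from 100.2 ± 32.9 to 564 ± 337 CPM (adjusted p = 0.0826) while C3 went from 321 ± 75.6 to 537 ± 105 CPM (adjusted p = 0.458). Cd68 went from 9.49 ± 4.03 to 134 ± 78.1 CPM (adjusted p = 0.114).

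MHC class II genes were higher, with 0 of 17 genes passing (14 higher and 0 lower adjusted over the list alone). Their median was 1.89 (camera adjusted p = 3.19e-14, adjusted p = 0.125 with an estimated correlation). Cd74 was at 445, 464 and 1771 CPM at 7 d. MHC class I genes had 0 of 23 genes passing (4 higher and 0 lower adjusted over the list alone). Their median was 0.64 (camera adjusted p = 2.37e-06, adjusted p = 0.319 with an estimated correlation). Interferon-stimulated genes had 0 of 44 genes passing (0 adjusted over the list alone). Their median was 0.66 (camera adjusted p = 8.48e-10, adjusted p = 0.266 with an estimated correlation). T cell markers had 0 of 19 genes passing (3 higher and 0 lower adjusted over the list alone). Their median was 1.60 (camera adjusted p = 1.84e-08, adjusted p = 0.242 with an estimated correlation). Cd6 went from 3.13 ± 1.11 to 13.4 ± 2.68 CPM (adjusted p = 0.0759). B and plasma cell markers had 1 of 6 genes higher, 0 lower and 5 not passing (3 higher and 0 lower adjusted over the list alone). Their median was 1.09 (camera adjusted p = 8.68e-04, adjusted p = 0.125 with an estimated correlation), a call lost on ranks (0.0746). The member that rose, Blnk (log2 2.01 ± 0.31, adjusted p = 0.0433), is an adaptor of the B cell receptor that myeloid cells also express.

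Cell cycle genes were higher, with 0 of 50 genes passing (28 higher and 0 lower adjusted over the list alone). Their median was 1.71 (camera adjusted p = 1.13e-17, adjusted p = 0.265 with an estimated correlation). Ribosomal protein genes had 0 of 84 genes passing (0 adjusted over the list alone, median 0.75, camera adjusted p = 1.52e-22, adjusted p = 0.344 with an estimated correlation), with a positive median under each scaling tried, at 0.75 and 0.77 under the others (length-corrected 0.39). The correlation of fold change with gene length across 11273 genes was −0.434. Neutrophil markers were still higher, with 0 of 15 genes passing (4 higher and 0 lower adjusted over the list alone). Their median was 1.60 (camera adjusted p = 8.51e-06, adjusted p = 0.344 with an estimated correlation). Their median was also 1.60 with Mmp8, at 0 counts in control, at its bound. S100a9 was at 1.46, 1.32 and 1.01 CPM (log2 1.60 ± 1.02, adjusted p = 0.488) and Lcn2 went from 2.64 ± 1.33 to 16.5 ± 8.21 CPM (adjusted p = 0.102). Cytokine genes had 0 of 28 genes passing (2 higher and 0 lower adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.0334, adjusted p = 0.593 with an estimated correlation), a call lost without control replicate 2 (0.123) or 7 d replicate 3 (0.0544) and length-corrected (0.103, median 0.18). The IL-6 and STAT3 list had 0 of 24 genes passing (5 higher and 1 lower adjusted over the list alone). Their median was 0.96 (camera adjusted p = 3.86e-06, adjusted p = 0.265 with an estimated correlation).

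Reactive astrocyte genes were higher at 7 d, with 1 of 26 genes higher, 0 lower and 25 not passing (9 higher and 0 lower adjusted over the list alone). Their median was 0.60 (camera adjusted p = 1.20e-08, adjusted p = 0.125 with an estimated correlation). Astrocyte markers were lower, with 0 of 25 genes passing (0 adjusted over the list alone). Their median was −0.22 (camera adjusted p = 0.0191, adjusted p = 0.598 with an estimated correlation), a call lost without 7 d replicate 1 (0.320). Aqp4 went from 2931 ± 1549.9 to 1406 ± 859 CPM (adjusted p = 0.456), Gfap from 5868 ± 1108 to 5392 ± 1127 CPM (adjusted p = 0.881) and Kcnj10 from 522 ± 38.5 to 299 ± 15.5 CPM (adjusted p = 0.214). Water and ion transport genes were lower, with 0 of 22 genes passing (0 adjusted over the list alone). Their median was −0.28 (camera adjusted p = 0.0314, adjusted p = 0.568 with an estimated correlation), a call lost without control replicate 2 (0.0630) or 7 d replicate 1 (0.245) and length-corrected (0.0610). Neuronal markers were lower, with 0 of 15 genes passing (0 higher and 3 lower adjusted over the list alone). Their median was −0.51 (camera adjusted p = 2.24e-04, adjusted p = 0.125 with an estimated correlation). The axonal injury list was lower, with 0 of 19 genes passing (0 higher and 2 lower adjusted over the list alone). Their median was −0.24 (camera adjusted p = 0.0407, 0.227 with an estimated correlation). The list lost the call without control replicate 1 or 3 or 7 d replicate 2 (0.0619 to 0.0802), on ranks (0.126) and unfiltered (0.0581). It holds the neurofilaments: Nefh went from 661 ± 405 to 152 ± 51.1 CPM (adjusted p = 0.101), Nefm from 108 ± 63.4 to 29.2 ± 18.7 CPM (adjusted p = 0.192) and Nefl from 26.4 ± 13.9 to 7.34 ± 3.89 CPM (adjusted p = 0.160).

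Mitochondrially encoded genes were lower (median −0.38, camera adjusted p = 0.0185, adjusted p = 0.589 with an estimated correlation; length-corrected median −0.71), a call lost without control replicate 2 (0.123). The retinal list was lower (median −1.80, camera adjusted p = 0.0487, adjusted p = 0.243 with an estimated correlation), a call lost without control replicate 2 (0.117), the library with the highest sum of that list, or 7 d replicate 2 (0.0827) and on ranks (0.0746). Camera called 32 of 48 lists in all, 24 higher and 8 lower; with an estimated correlation camera called 0 lists and fry called 8.

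**Figure D2:**
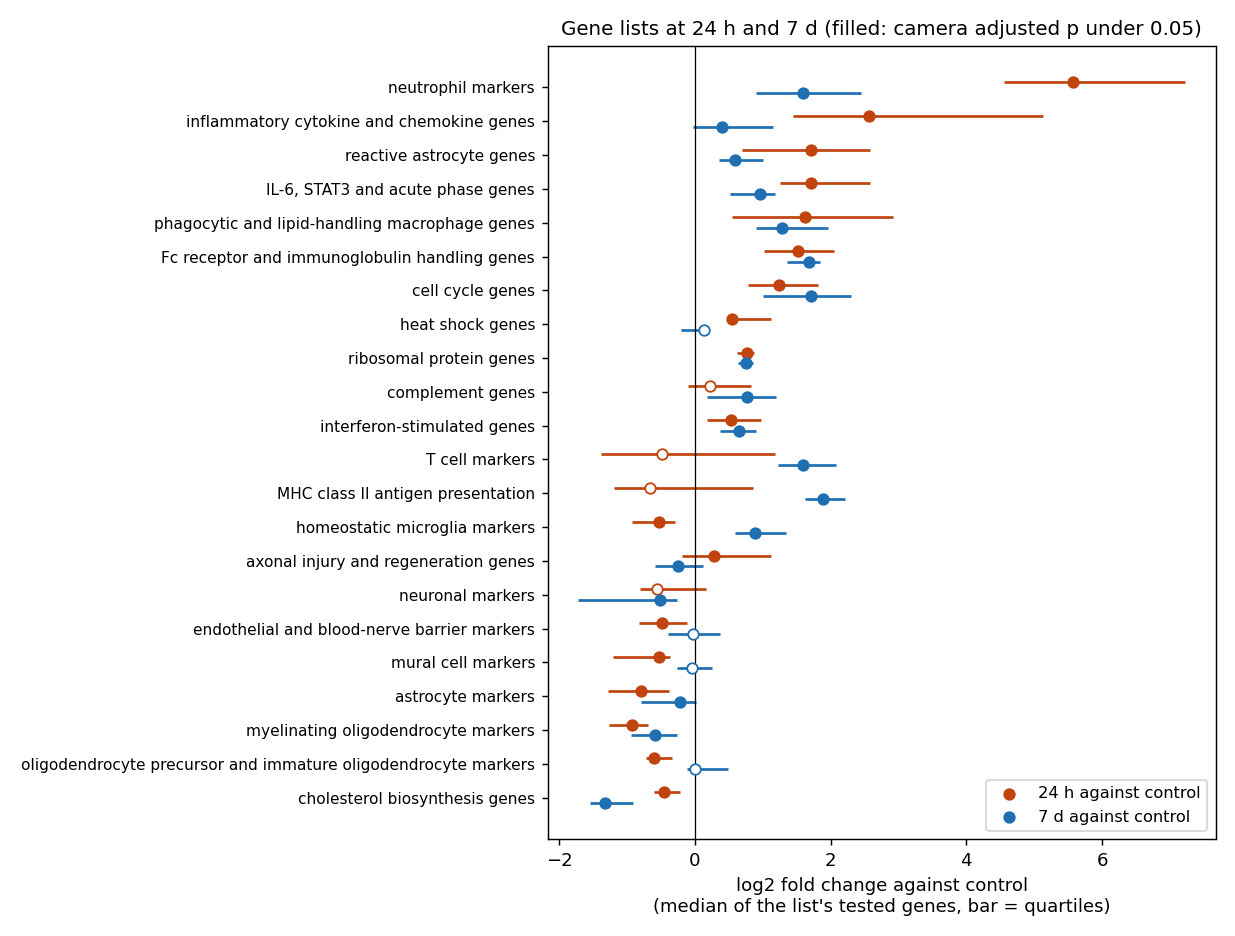
Median log2 fold change against control of 22 gene lists at 24 h and at 7 d, with bars from the lower to the upper quartile of each list's tested genes; filled points passed camera's preset-correlation test at an adjusted p under 0.05. Neutrophil markers had medians of 5.58 and 1.60, homeostatic microglia markers −0.52 and 0.88.

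The third comparison asked what differed between 7 d and 24 h, and it also tests whether the changes at the 2 times differ in size. At 7 d, 6 of 28 inflammatory cytokine genes and 3 of 15 neutrophil markers were lower than at 24 h, and 5 of 17 homeostatic microglia markers and 4 of 17 MHC class II genes were higher. Ccl2 fell from 188 ± 181 to 2.09 ± 0.958 CPM (log2 −6.48 ± 0.86, adjusted p = 0.0160). Gldn fell from 137 ± 49.9 to 2.65 ± 0.575 CPM (log2 −5.70 ± 0.36, adjusted p = 2.90e-04). Cd74 rose from 80.0 ± 6.11 to 894 ± 760.2 CPM (log2 3.48 ± 0.61, adjusted p = 0.0317). Trem2 rose from 13.1 ± 3.54 to 111 ± 62.3 CPM (log2 3.09 ± 0.44, adjusted p = 0.0192).

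In this comparison 201 genes passed, 105 higher at 7 d and 96 lower, 103 and 96 of them by at least 2-fold. An unadjusted p under 0.05 was found for 2884 genes, and the libraries of the 2 groups did not overlap in 22.3% of genes, against 10% by chance. The count was 33 and 56 without control replicates 1 and 3, 61 and 23 without 24 h replicates 1 and 3, and 39, 88 and 28 without 7 d replicates 1, 2 and 3. On all libraries DESeq2 called 1246 genes, limma on unfiltered FPKM 79, and edgeR 30 with only these 2 groups in the fit. Among alternatives chosen after seeing the data, edgeR called 378 with the trend with gene length removed, 33 without control replicate 2 and 24 h replicate 1, and 13 without 24 h replicate 3 and 7 d replicate 3. Of 53 named genes that passed, Gldn, Mmp3, Cxcl1, Hbegf, Gal, Cd34, Tmem150c, Myo5b and Clcf1 kept the call whichever library was left out.

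The largest falls were those of Ccl7, Ccl2, Myo5b, Ucn2, Gldn, Slpi, Mmp3 and S100a8. Ccl7, a chemokine of monocytes, fell from 68.2 ± 80.3 to 0.529 ± 0.396 CPM (log2 −7.02 ± 1.25, adjusted p = 0.0337). Myo5b, an unconventional myosin, fell from 12.6 ± 4.70 to 0.155 ± 0.0797 CPM (log2 −6.31 ± 0.62, adjusted p = 0.00840), and Mmp3 fell (log2 −5.51 ± 0.68, adjusted p = 0.0108). The cytokine list was lower, with 0 of 28 genes higher, 6 lower and 22 not passing (0 higher and 16 lower adjusted over the list alone). Their median was −2.08 (camera adjusted p = 2.24e-11, adjusted p = 0.212 with an estimated correlation). Neutrophil markers were lower, with 0 of 15 genes higher, 3 lower and 12 not passing (0 higher and 12 lower adjusted over the list alone). Their median was −4.25 (camera adjusted p = 1.63e-07, adjusted p = 0.382 with an estimated correlation). S100a9 fell (log2 −5.22 ± 1.06, adjusted p = 0.0487). Reactive astrocyte genes were lower, with 0 of 26 genes higher, 6 lower and 20 not passing (0 higher and 17 lower adjusted over the list alone). Their median was −1.34 (camera adjusted p = 2.60e-11, adjusted p = 0.0527 with an estimated correlation). Timp1 fell (log2 −2.57 ± 0.39, adjusted p = 0.0267) and the annexin partner S100a10 fell (log2 −1.80 ± 0.31, adjusted p = 0.0306). Heat shock genes had 0 of 17 genes higher, 1 lower and 16 not passing (0 higher and 9 lower adjusted over the list alone, median −0.74, camera adjusted p = 7.35e-08, adjusted p = 0.171 with an estimated correlation). Immediate early genes had 0 of 25 genes higher, 2 lower and 23 not passing (0 higher and 5 lower adjusted over the list alone). Their median was −0.78 (camera adjusted p = 5.41e-06, adjusted p = 0.382 with an estimated correlation). Axonal injury genes had 0 of 19 genes higher, 2 lower and 17 not passing (0 higher and 7 lower adjusted over the list alone). Their median was −0.82 (camera adjusted p = 1.21e-05, adjusted p = 0.0527 with an estimated correlation). Gal fell (log2 −4.10 ± 0.55, adjusted p = 0.0162) and Arg1 (log2 −4.67 ± 0.80, adjusted p = 0.0306).

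IL-6 and STAT3 genes had 0 of 24 genes higher, 1 lower and 23 not passing (0 higher and 10 lower adjusted over the list alone, median −0.83, camera adjusted p = 3.32e-05, adjusted p = 0.382 with an estimated correlation) and NF-kB genes 0 of 19 genes higher, 2 lower and 17 not passing (0 higher and 8 lower adjusted over the list alone). Their median was −0.57 (camera adjusted p = 7.52e-05, adjusted p = 0.463 with an estimated correlation). Cholesterol genes were lower at 7 d, with 0 of 24 genes higher, 1 lower and 23 not passing (0 higher and 12 lower adjusted over the list alone). Their median was −0.78 (camera adjusted p = 1.81e-10, adjusted p = 0.357 with an estimated correlation). Hbegf fell (log2 −1.95 ± 0.21, adjusted p = 0.00840), Clcf1 (log2 −4.58 ± 0.48, adjusted p = 0.00840) and Ldha (log2 −1.99 ± 0.30, adjusted p = 0.0262). Extracellular matrix genes moved both ways, with 1 of 36 genes higher, 4 lower and 31 not passing (2 higher and 7 lower adjusted over the list alone, median 0.11, camera adjusted p = 0.357) and a mean of −0.38 (camera's direction was down), and passed as lower without 24 h replicate 2 (0.0270) or 7 d replicate 1 (0.00337); Thbs1, thrombospondin, fell (log2 −5.21 ± 0.93, adjusted p = 0.0337) and Lox (log2 −2.39 ± 0.40, adjusted p = 0.0303).

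Homeostatic microglia markers were higher at 7 d than at 24 h, with 5 of 17 genes higher, 0 lower and 12 not passing (15 higher and 0 lower adjusted over the list alone). Their median was 1.53 (camera adjusted p = 7.99e-18, adjusted p = 0.0527 with an estimated correlation). Cx3cr1 rose from 22.0 ± 6.44 to 92.5 ± 26.8 CPM (log2 2.07 ± 0.31, adjusted p = 0.0262) and the purinergic receptor P2ry13 (log2 2.14 ± 0.39, adjusted p = 0.0347). MHC class II genes were higher, with 4 of 17 genes higher, 0 lower and 13 not passing (13 higher and 0 lower adjusted over the list alone). Their median was 2.37 (camera adjusted p = 7.46e-12, adjusted p = 0.149 with an estimated correlation). The class II chains RT1-Da (log2 3.39 ± 0.62, adjusted p = 0.0346) and RT1-Db1 (log2 4.16 ± 0.79, adjusted p = 0.0393) rose with the protease Ctss (log2 2.37 ± 0.43, adjusted p = 0.0346). These chains belong to a gene family with similar sequences, so counts may be shared between members. T cell markers had 1 of 19 genes higher, 0 lower and 18 not passing (10 higher and 0 lower adjusted over the list alone). Their median was 1.95 (camera adjusted p = 8.56e-08, adjusted p = 0.338 with an estimated correlation). Cd4, which rat macrophages also express, rose (log2 3.09 ± 0.57, adjusted p = 0.0361). B and plasma cell markers had 2 of 6 genes higher, 0 lower and 4 not passing (4 higher and 0 lower adjusted over the list alone). Their median was 2.03 (camera adjusted p = 5.16e-05, adjusted p = 0.0527 with an estimated correlation). The survival receptor Tnfrsf13c rose (log2 4.07 ± 0.61, adjusted p = 0.0262). Complement genes had 2 of 30 genes higher, 0 lower and 28 not passing (4 higher and 0 lower adjusted over the list alone). Their median was 0.42 (camera adjusted p = 0.00264, adjusted p = 0.382 with an estimated correlation). C3 rose from 93.6 ± 54.5 to 537 ± 105 CPM (log2 2.52 ± 0.46, adjusted p = 0.0347).

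Phagocytic macrophage genes had 2 of 26 genes higher, 1 lower and 23 not passing (4 higher and 7 lower adjusted over the list alone, median −0.05, camera adjusted p = 0.903) and a mean of −0.30 (camera's direction was up), with Trem2 and Ctss higher and Msr1 lower (log2 −3.58 ± 0.61, adjusted p = 0.0306). Monocyte and macrophage markers had 1 of 25 genes higher, 2 lower and 22 not passing (3 higher and 3 lower adjusted over the list alone, median 0.11, camera adjusted p = 0.781) and a mean of −0.28 (camera's direction was up), and Adgre1, the F4/80 antigen, rose (log2 1.96 ± 0.36, adjusted p = 0.0346) while Cd14 fell (log2 −1.93 ± 0.36, adjusted p = 0.0368). Mural cell markers were higher, with 2 of 16 genes higher, 0 lower and 14 not passing (5 higher and 0 lower adjusted over the list alone). Their median was 0.66 (camera adjusted p = 1.26e-05, adjusted p = 0.145 with an estimated correlation). Rgs5 rose (log2 2.24 ± 0.35, adjusted p = 0.0292). The endothelial list was higher, with 1 of 23 genes higher, 0 lower and 22 not passing (1 higher and 0 lower adjusted over the list alone). Their median was 0.37 (camera adjusted p = 0.00306, adjusted p = 0.382 with an estimated correlation). The tight junction protein Ocln rose (log2 1.36 ± 0.26, adjusted p = 0.0379). Oligodendrocyte precursor markers were higher, with 0 of 19 genes passing (4 higher and 0 lower adjusted over the list alone). Their median was 0.58 (camera adjusted p = 3.51e-05, adjusted p = 0.145 with an estimated correlation). Astrocyte markers (median 0.60, camera adjusted p = 0.00404, adjusted p = 0.495 with an estimated correlation) and myelinating oligodendrocyte markers (median 0.41, camera adjusted p = 0.00412, adjusted p = 0.560 with an estimated correlation) were higher, but not without 24 h replicate 3 (0.180 and 0.457), the library with the lowest sum of the latter list. Cell cycle genes had 0 of 50 genes higher, 1 lower and 49 not passing (3 higher and 9 lower adjusted over the list alone, median 0.23, camera adjusted p = 0.421) and a mean of 0.16 (camera's direction was down), with Mcm3 lower (log2 −1.62 ± 0.29, adjusted p = 0.0337), and passed as lower without 7 d replicate 1 (0.000852). Erythrocyte markers were lower (median −1.74, camera adjusted p = 0.00315, adjusted p = 0.475 with an estimated correlation), with sums of 225, 227 and 991 CPM at 7 d. Skeletal muscle markers were lower (median −3.45, camera adjusted p = 0.00491, adjusted p = 0.634 with an estimated correlation), but higher without 24 h replicate 1 (0.0163). In all, camera called 33 of 48 lists, 14 higher and 19 lower; with an estimated correlation camera called 0 and fry called 7.

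**Figure D3:**
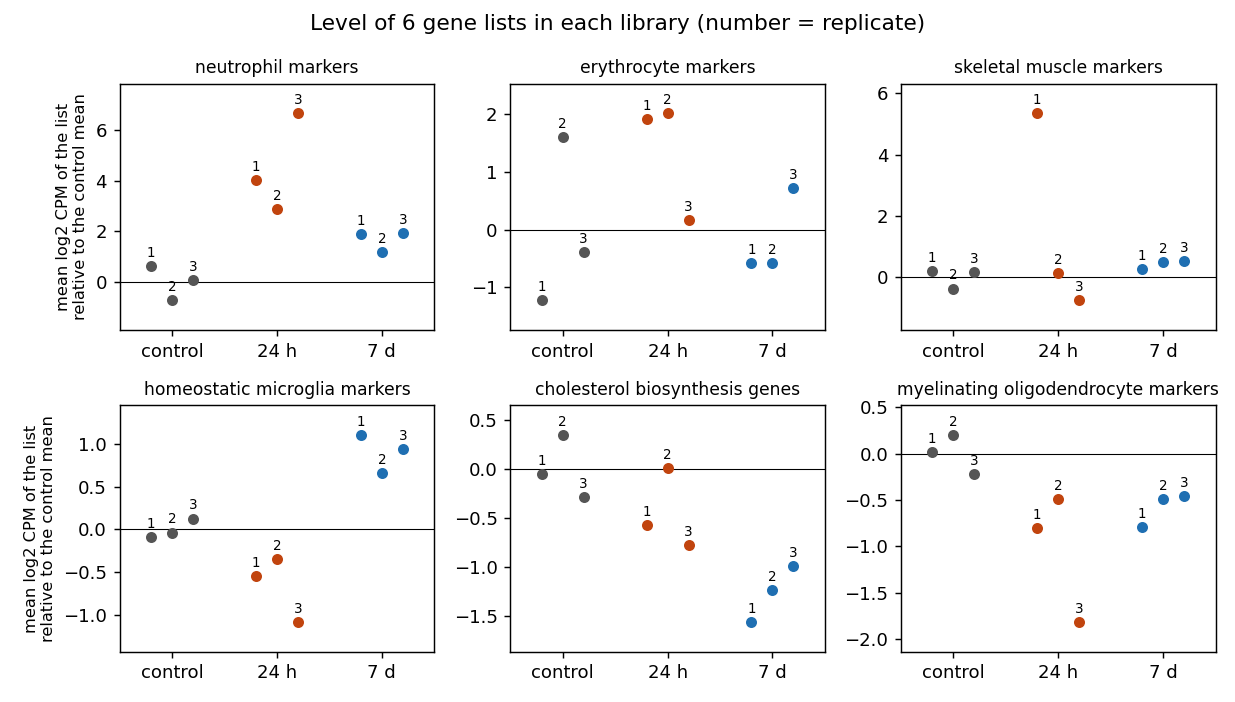
Mean log2 CPM of 6 gene lists in each library relative to the mean of the control libraries, with the replicate number beside each point. Neutrophil markers stood above control in each 24 h and 7 d library, whereas skeletal muscle markers stood apart in 24 h replicate 1 alone.

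Changes at the 2 times were then set against each other. Across the 16744 genes, which are not independent replicates, log2 fold changes at 24 h and 7 d had a correlation of 0.599. Both use the same 3 control libraries, and unchanged groups simulated against shared controls gave 0.502 on average (0.482 to 0.523 in 40 simulations). The covariance was 0.536 against 0.149 simulated, and 73.0% of genes had the same sign against 66.8%. Genes that passed at both times numbered 9, all higher: Clec12a, Gldn, Htatip2, Mmp12, Myo7a, Plau, S100a4, Timp1 and Trim55. At an unadjusted p under 0.05, 1142 genes passed at both times with the same sign and 36 with opposite signs, against 176 (151 to 211) and 1.43 in the simulations. Independent lists would share 1.11 higher and 0.0628 lower genes; the controls are too few to be split, so part of any excess may come from them. The 9 became 26 without 24 h replicate 3, 39 without 7 d replicate 2 and 0 without any other library.

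Of 643 genes higher at 24 h, 618 had a smaller change at 7 d and 602 kept their sign. Their log2 medians were 1.83 and 0.68, and 87 differed between the times. Of 263 genes lower at 24 h, 258 had a smaller change and 243 kept their sign, with medians of −1.40 and −0.57; 18 differed. Simulated unchanged groups, again with genes varying independently, show both patterns, in fewer genes. Of as many genes with the smallest p each way at 24 h, 580.4 (566 to 600) and 228 (214 to 241) kept their sign. A smaller change was seen in 543 (527 to 557) and 244 (233 to 255). Of the 33 genes called at 7 d, 24 were not called at 24 h, and 21 differed between the times.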

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

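The tests of the explanations for neutrophil, cholesterol and ribosomal genes were chosen after the results were seen; the comparison of the times and the other splits of the libraries were planned.

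By the test of the difference, the changes against control differed between the times for 201 genes and 33 lists (0 with an estimated correlation). These named genes had opposite signs against control at the times and a difference that passed (log2 fold change of 7 d against 24 h). Higher at 7 d were RT1-Db1 (4.16), Tnfrsf13c (4.07), Cd74 (3.48), RT1-Da (3.39), Apoc1 (3.26), Ltc4s (3.22), Tmem150c (3.14), Trem2 (3.09), Cd4 (3.09), Cd34 (2.84), C3 (2.52), Ctss (2.37), Myl9 (2.16), P2ry13 (2.14), Cx3cr1 (2.07), Adgre1 (1.96), C4a (1.95) and Ocln (1.36). Lower at 7 d were Ccl7 (−7.02), Ccl2 (−6.48), Myo5b (−6.31), Thbs1 (−5.21), Arg1 (−4.67), Gal (−4.10) and Hspb8 (−1.46). Camera called homeostatic microglia markers (median 1.53 here) and axonal injury genes (−0.82) against control at both times, in opposite directions. MHC class II genes and other lists had medians of opposite sign but were not called at both times. Gene signs are of fitted values, passed or not.

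The 3 against 3 comparisons have 10 splits each, too few for a share under 0.05. The real split gave 906 genes at 24 h, 33 at 7 d and 201 between the times, and the highest other split gave 0, 1 and 0, so that 1 split, the real one, gave as many in each. For lists, the real splits gave 34, 32 and 33 and the highest others 36, 27 and 32, so that 2, 1 and 1 of the 10 gave as many: camera with a preset correlation also called many lists in arbitrary splits of these libraries. For any difference among the 3 groups, 100 of the 280 splits were drawn, the real one included. Of these, 1, the real one, gave as many as 751 genes, and the highest other gave 45. That is the smallest share that 100 splits can give. A chance split of the libraries is thus unlikely to give that count, but the splits not drawn were not tested.

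Neutrophil markers at 24 h stood against the erythrocyte markers, which were higher too (adjusted p = 0.275 and 0.560 with an estimated correlation). More blood of the same makeup in the nerves would raise both lists alike, and the neutrophil median exceeded the erythrocyte median by 4.34 (2.56 without control replicate 2 to 5.24 without control replicate 1). Per library, the difference of the list levels was 1.87, −2.32 and 0.44 in the controls and 2.12, 0.87 and 6.51 at 24 h, so the groups overlapped. Blood in the tissue therefore stays open as part of the pattern, as does an entry of neutrophils after the serum or the injection, which may each contribute and were not tested apart.

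Cholesterol biosynthesis genes were lower at 7 d (adjusted p = 0.125 with an estimated correlation). A lower share of oligodendrocyte RNA would lower them as much as the myelinating oligodendrocyte markers, but their median lay lower, with a difference of −0.73 (−0.84 without 7 d replicate 3 to −0.63 without control replicate 2), and per library −0.76, −0.75 and −0.52 at 7 d against −0.07, 0.14 and −0.07 in the controls. Gene length does not account for it either: the median of −1.32 lay below those of 10000 random lists matched on length (95% from −0.21 to 0.25), and it was −1.36 with the length trend removed. A lower activity of sterol synthesis in the model is a hypothesis that stays open, and a change in other cell types that make sterols may also contribute.

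Ribosomal protein genes were higher at both times (adjusted p = 0.373 and 0.344 with an estimated correlation), and short genes were higher than long ones. Their medians of 0.77 at 24 h and 0.75 at 7 d lay above those of length-matched lists (95% from 0.24 to 0.61 and from 0.20 to 0.45), which argues against gene length as the whole cause. The matched lists had medians of 0.43 and 0.33, and with the trend removed the list medians were 0.36 and 0.39, so length may account for part. RNA quality and the cell makeup of the tissue were not tested and stay open.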

How the results depend on the processing

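The alternatives that remove 2 libraries, the length trend or background genes were chosen after seeing the data; the others were planned. Where a value moved, the cause was not tested unless stated.

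DESeq2 size factors, upper-quartile scaling and a stricter filter kept each count of changed genes within 1.5 times, and the largest shift of the median of all genes was 0.06. The FPKM with a filter gave 90 genes at 7 d with either pseudocount. Without a filter on counts, edgeR called 84 at 7 d; without one on FPKM, limma called 325 at 24 h, 0 at 7 d (2563 at an unadjusted p under 0.05), 79 between the times and 155 among the 3 groups. DESeq2's test called 2581, 806, 1246 and 2775 genes for the same 4 results, and limma-voom with quality weights 1400, 428, 191 and 1564. With only the groups compared in the fit, and so fewer residual degrees of freedom, edgeR called 616, 1 and 30.

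Same-numbered libraries deviated from their group means with correlations of −0.22 to 0.32. Differently numbered ones had −0.35 to 0.31, so the check cannot tell whether numbers pair the libraries. With the replicate number as a block, edgeR called 751 genes at 24 h, 177 at 7 d, 127 between the times and 682 among the 3 groups, and camera called 34, 30 and 35 lists.

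Leaving out each library in turn gave 35 to 1213 genes at 24 h, 0 to 181 at 7 d, 23 to 199 between the times, 155 to 645 among the 3 groups and 0 to 39 shared by both times; the lists called were 28 to 37, 29 to 32 and 27 to 35. Of 125 named genes, 85 passed at 24 h, 18 at 7 d and 53 between the times; 16, 0 and 9 did so whichever library was left out, and 45, 0 and 13 under all other alternatives fixed beforehand that tested them. No named gene passed in opposite directions.

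Without control replicate 2 and 24 h replicate 1, edgeR called 204, 0 (1429 at an unadjusted p under 0.05), 33 and 80 genes, with 0 shared by both times. Without 24 h replicate 3 and 7 d replicate 3 it called 279, 2, 13 and 209, with 1 shared. With the length trend removed it called 992, 38, 378 and 960. At an adjusted p under 0.01, 0 genes were shared. Camera with an estimated correlation called 1, 0 and 0 lists, and fry called 17, 8 and 7, against 34, 32 and 33 with the preset.

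The direction turned for skeletal muscle markers without 24 h replicate 1, the library that holds the muscle transcripts. At 24 h the adjusted p was then 0.347 (1.14e-10 without 24 h replicate 3 to 0.347 over the left-out libraries), and 0.160 with control replicate 2 also left out. Between the times it was then 0.0163 (1.01e-10 without 24 h replicate 3 to 0.0229 without 7 d replicate 1) and 0.0120. It also turned for erythrocyte markers at 7 d without control replicate 2, the control with the most of them, with an adjusted p of 0.0282 (up to 0.917 without 7 d replicate 1), and 0.0216 with 24 h replicate 1 also left out. Of the called lists, 28 of 34, 23 of 32 and 20 of 33 kept the call whichever library was left out. Genes near the floor, such as Il6, were tested only without the count filter.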

Other observations

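The description of these values was chosen after the results were seen, and no explanation was tested for them.

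Oxt and Avp, which encode oxytocin and vasopressin, were highest in the controls. Avp was at 15.7, 0.535 and 4.94 CPM in the controls, at most 0.0262 CPM at 24 h and at 0, 0 and 1.29 CPM at 7 d. The haemoglobin gene Hba-a1 was highest, at 1167 CPM, in 24 h replicate 2.

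The trend with gene length differed between libraries. In 24 h replicate 2 the shortest eighth of genes had a median of 0.68 and the longest eighth −0.59, in 7 d replicate 3 they had 0.69 and −0.78, and in control replicate 2 they had −0.23 and 0.28.

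Of the 201 genes that differed between the times, 77 passed against control at neither time, 105 passed at 24 h and 21 at 7 d, and 114 had opposite signs against control.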
